A study of Mus musculus with 6 samples.

How the data were processed

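Gene expression was measured in 6 stable lines of ZHBTc4 cells, a mouse embryonic stem cell line in which the resident Oct4 transgene is shut off by tetracycline. Per the labels' protocols, cells were electroporated with a plasmid encoding a POUV protein and plated in medium with tetracycline at 2 µg/mL. Puromycin at 1 µg/mL was added from day 2, and colonies were picked at day 9 for expansion. The rescuing proteins were mouse OCT4 (mOct4, clones 1 and 2), coelacanth POU5F1 (LcPOU5F1, clones 4 and 5) and coelacanth POU5F3 (LcPOU5F3, clones 1 and 2). The labels give an RNA integrity number of 10 for the RNA.

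Each sample was hybridised to a 1-colour Agilent array of 55681 non-control probes on 59305 spots. Per the file headers, spot intensity was extracted by the authors with Agilent Feature Extraction 11.0.1.1 and protocol GE1_1100_Jul11, and the processed intensity is linear, background-subtracted and detrended, with no scaling between arrays. The deposited series matrix holds the same linear intensity values, rounded, with no further scaling or centring found when each column was set against its array. The scanner software also wrote flags for signals well above background, saturation and outlying spots, per the file headers. The array design names the mouse build mm9.

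Processed signals were log2 transformed and each array's 75th percentile was subtracted. Control spots and outlier-flagged spots were left out, and spots of 1 probe were averaged. A probe was kept if it was well above background on both arrays of at least 1 group. Accessions were matched without versions to a RefSeq table of the GRCm38.p6 assembly, used for names only. This named 27656 probes with 1 gene symbol and left 28025 (50.3%) unnamed. Of 30944 kept probes, 12026 had no symbol, and 5 probes with an incomplete value were dropped. For the 3630 genes with more than 1 kept probe, the probe with the highest mean over the arrays was used, which gave 14595 genes.

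The 3 group means were fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 3 residual degrees of freedom and 5.16 after moderation. P-values were adjusted by Benjamini-Hochberg and called under 0.05. With 2 clones per group, p-values measure the spread between separately picked clones, and the number of arrays limits the precision. A total of 24 gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Members of a list were also counted after adjustment over the list alone.

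The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The rule named, per comparison, the 10 highest and 10 lowest genes past the threshold whose clones did not overlap and that had a proper symbol. It added up to 4 members per list with the smallest p, and Pou5f1, Nanog, Sox2, Klf4, Esrrb, Zfp42, Cdx2, Gata6, T, Fgf5 and Cdh1 whatever their values. Some genes that the rule names are not reported here. A probe not well above background on any array of a group has only a bound there. Such ratios are given as "at least N-fold". They set the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest well-above-background signal and the probe's own signal. In list medians with unmeasured members at their bounds, members for which no such ratio could be given keep their measured value.

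The median spot intensity was used for normexp background correction with an offset of 50, because the planned mean intensity was not among the columns used here. A variance weight per group and a common floor on dim signals were added after the data were seen. Other alternatives were quantile normalization, centring on the median, no filter, a stricter filter, every kept probe, an intensity trend, only the 4 arrays compared, other thresholds, the series matrix, the slide as a block, a replicate block, and each array left out. Slide 1 held 5 arrays and slide 2 held only mOct4 clone 2, so the slide block equals leaving out that clone.

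The steps were tested on simulated data over 14595 genes with 200 changed genes. Each gene's pooled spread was scaled by a ratio that was the same for all genes of a group. Spread particular to a gene in a group was left out, so recovery in the real data may be lower. With each group's measured spread, the fit of LcPOU5F3 against mOct4 recovered 79.1% of genes changed by 2 on the log2 scale and 16.4% of those changed by 1, with 15 false calls. For LcPOU5F1 against mOct4 it recovered 77.6% and 5.97%, with 0 false calls. For LcPOU5F1 against LcPOU5F3 it recovered 79.1% and 11.9%, with 15 false calls.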

Results

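The data describe how mouse embryonic stem cells express their genes when a coelacanth POUV protein replaces mouse OCT4, the POU-domain factor that keeps these cells pluripotent. The series asks how far each of the coelacanth paralogs, POU5F1 and POU5F3, can serve in that place. Each group held 2 clones with 1 array each. Between 43.5% and 57.8% of probes were well above background on an array, with the highest shares in the mOct4 clones (57.5% and 57.8%) and lower ones in the LcPOU5F1 clones (48.1% and 43.7%) and the LcPOU5F3 clones (43.5% and 53.3%). No spot was saturated, and the coefficient of variation of replicated probes lay between 4.25% and 4.58%. Log2 fold changes are given with their standard errors from limma, and each mean is over n = 2 clones.

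The mouse Pou5f1 transcript was examined first, since only the mOct4 clones carry the mouse protein as the rescuing factor. The single kept probe named Pou5f1 was well above background on both mOct4 arrays and on no array of the coelacanth-rescued clones. Its mean in the mOct4 clones was -1.62 ± 0.19 (SD, n = 2) relative to the 75th percentile. Pou5f1 was at least 2.18-fold higher in the mOct4 clones than in the LcPOU5F1 clones and at least 2.98-fold higher than in the LcPOU5F3 clones. These bounds use each array's own floor. Smaller log2 fold changes came from a common floor (-0.82 for both coelacanth groups) and from normexp (-0.71 for LcPOU5F1 and -0.94 for LcPOU5F3). Neither difference passed limma's test after Benjamini-Hochberg adjustment (adjusted p = 0.26 and 0.07). Where the probe lies in the transcript is not given in the sources used here, so it cannot separate the transgene from other Pou5f1 transcripts.

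To find what coelacanth POU5F3 changes relative to mouse OCT4, the LcPOU5F3 clones were compared with the mOct4 clones. Genes of the naive pluripotent state fell: Esrrb, an orphan nuclear receptor of that state, was 5.58-fold lower (log2 fold change -2.48 ± 0.40), Zfp42 4.74-fold lower and Nanog 4.12-fold lower. Keratins of simple epithelia and of the trophectoderm, the outer layer of the blastocyst, rose, with Krt8 56.5-fold higher (5.82 ± 0.18) and Krt18 43.6-fold higher (5.45 ± 0.30). Cdx2, a transcription factor of the trophectoderm, rose 14.1-fold (3.82 ± 0.77). The adhesion gene Cdh1 rose 4.01-fold (2.00 ± 0.38). In all, limma with Benjamini-Hochberg adjustment called 3438 of 14595 genes, 1723 higher and 1715 lower, of which 2312 changed by at least 2-fold.

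Of 23 naive pluripotency genes, 17 fell, 1 rose and 5 did not pass the test, and adjusted over the list alone 20 fell and 1 rose. Tcl1 fell 71.7-fold (-6.16 ± 0.77, with the clones at -5.03 and -7.3), Fbxo15 7.67-fold (-2.94 ± 0.34), Klf4 4.52-fold and Sox2 3.21-fold. The gene that rose was Dppa3, a maternal-effect gene expressed in naive and germ cells, at 7.61-fold (2.93 ± 0.30), although 1 of the 2 mOct4 arrays did not measure it well above background. A second Nanog probe gave -0.09 where the one used gave -2.04. Camera placed the naive list lower than other genes (adjusted p = 9.6e-07 after Benjamini-Hochberg, adjusted p = 0.37 with an estimated correlation). Among 20 general pluripotency genes, 11 fell and 1 rose, and adjusted over the list alone 12 fell and 2 rose. They included Foxd3 at 12.5-fold lower, Tdgf1, a co-receptor of Nodal signalling, at 7.46-fold lower and Dppa2 at 2.70-fold lower. Camera's call for that list (adjusted p = 0.005) was also lost with an estimated correlation (adjusted p = 0.62). Fry, which does not set a list against other genes, gave adjusted p = 0.011 for the naive list and 0.037 for the general list. In this comparison fry called 10 of the 11 lists that camera called at the preset correlation.

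Of 27 trophectoderm genes, 12 rose and none fell, and adjusted over the list alone 16 rose. Krt7 was 68.4-fold higher (6.10 ± 0.23), with 1 of the 2 mOct4 arrays well above background, and Krt19 was 20.1-fold higher (4.33 ± 0.32). Camera placed the list higher (adjusted p = 6.8e-07, and adjusted p = 0.37 with an estimated correlation). Of 23 epithelial adhesion genes, a list that shares Krt8 and Krt18 with the former, 15 rose and none fell, and adjusted over the list alone 18 rose. The desmosome gene Dsp was 15.6-fold higher and the protease gene Prss8 5.69-fold higher (camera adjusted p = 4.9e-09, and adjusted p = 0.47 with an estimated correlation). Genes of mesenchyme and extracellular matrix rose as well, in 10 of 20 members (also 10 adjusted over the list alone). Tagln, a smooth muscle actin-binding protein gene, was 49.7-fold higher, Timp3 22.1-fold higher and Ccn1 14.9-fold higher. Camera's adjusted p for that list was 0.00017, and adjusted p = 0.37 with an estimated correlation.

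**Figure D1:**
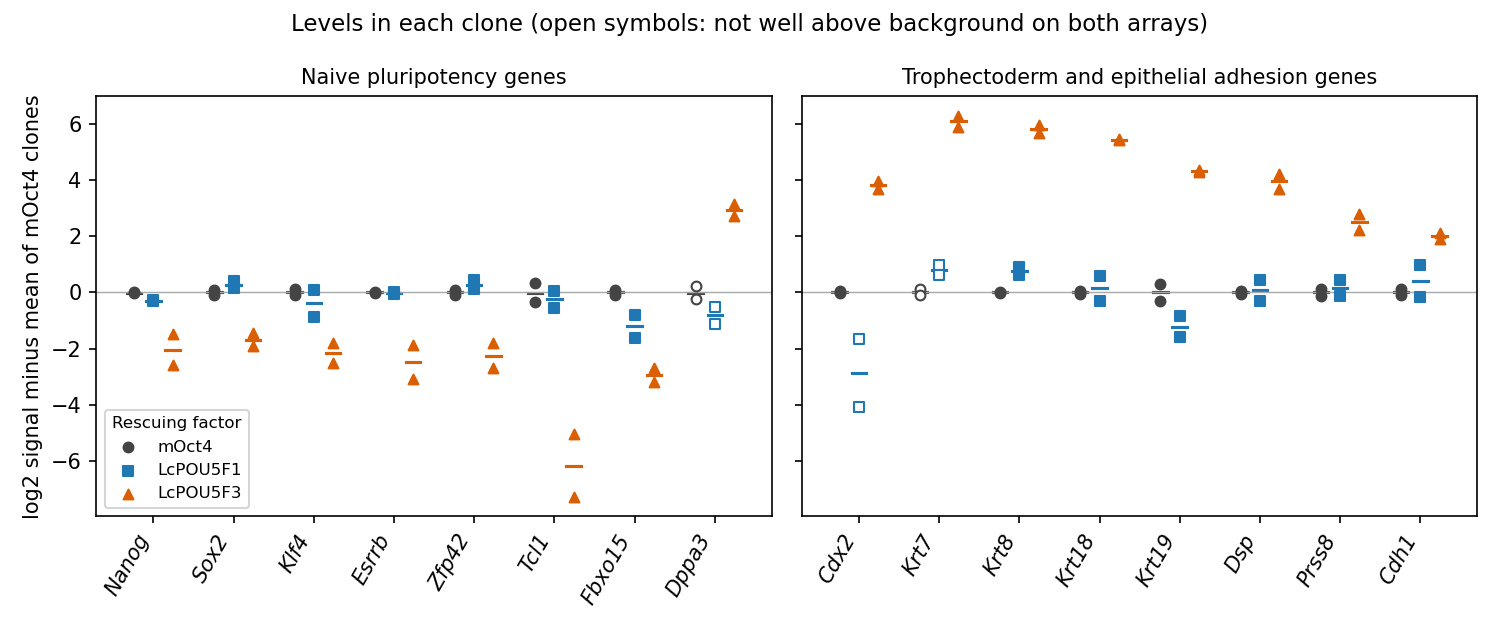
Log2 signal of each clone minus the mean of the mOct4 clones, for naive pluripotency genes (left) and for trophectoderm and epithelial adhesion genes (right), with a bar at each group's mean of 2 clones and open symbols where a group was not well above background on both arrays. The LcPOU5F3 clones lie below the other 4 clones for Nanog, Sox2, Klf4, Esrrb, Zfp42, Tcl1 and Fbxo15 and above them for Dppa3 and every gene on the right.

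Targets of p53 were mostly higher in the LcPOU5F3 clones, with 15 of 23 up and 2 down (16 up and 2 down adjusted over the list alone). Perp, also a desmosome gene, was 32.4-fold higher, Plk2 15-fold higher and the antiproliferative gene Btg2 10.1-fold higher. Camera's adjusted p was 7.4e-07, and adjusted p = 0.41 with an estimated correlation. Of 16 Hox genes, 6 rose and none fell (8 adjusted over the list alone), with Hoxc9 at least 52.1-fold higher and Hoxc6 17.0-fold higher (camera adjusted p = 0.00054, and adjusted p = 0.37 with an estimated correlation). Of 20 imprinted genes, 6 rose and 2 fell (7 and 2 adjusted over the list alone), with Dlk1 18.6-fold higher (camera adjusted p = 0.013, and adjusted p = 0.37 with an estimated correlation). Of 17 endoderm genes, 7 rose and 1 fell (10 and 3 adjusted over the list alone), with the endocytic adaptor Dab2 at least 20.4-fold higher and Lamb1 4.99-fold higher, while Amn fell 2.97-fold. Camera's adjusted p was 0.0078, and adjusted p = 0.37 with an estimated correlation. Of 28 cell cycle genes, 7 fell and none rose (12 adjusted over the list alone), by small amounts such as 1.91-fold for the replication helicase gene Mcm3 (camera adjusted p = 0.0016, and adjusted p = 0.41 with an estimated correlation). Of 15 genes in the 2-cell-like list, named for a rare totipotent-like state, Zfp352 (3.51-fold) and Tcstv1 (at least 1.77-fold) fell. Zfp809, well above background on both arrays of every group, rose 1.66-fold. Counts were equal when adjusted over the list alone. A second Zfp352 probe gave 0.44 where the one used gave -1.81. The list's median was -2.54, or -1.81 with unmeasured members at their bounds where these could be given (camera adjusted p = 0.023, and adjusted p = 0.7 with an estimated correlation). It was -0.15 over the 4 members well above background on all 6 arrays, which leaves out members that fell to background.

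The 10 called genes with the largest fitted rises, several of them unmeasured in the mOct4 clones, included Anxa1 at 299-fold (8.23 ± 0.61), Prss23 at least 53.2-fold and Sema3c at least 52.3-fold. A second Sema3c probe gave 4.91 where the one used gave 7.19. Csf1, Dppa1, Hoxc9, Fras1, Thbs1 and Mal were also among the 10. The 10 with the largest fitted falls included Tcl1 and Stmn3, the latter at least 29.1-fold lower. Stra8, a gene of meiotic entry, was 131-fold and Inhbb 54.5-fold lower, both with 1 of 2 LcPOU5F3 arrays well above background. The rest were Myo1f, Efcab10, Hrk, Gli1, Capn3 and Mcf2. Gata6, T and Fgf5, markers of endoderm, mesoderm and the primed epiblast, did not pass the probe filter and were not tested.

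These calls rest on the agreement of the mOct4 pair: limma called 35 genes without mOct4 clone 1 and 41 without mOct4 clone 2, which is also the value within slide 1, and neither fit called any naive pluripotency gene. The median of the naive list was -1.58 and -1.78 in these fits, against -1.68 with all arrays. Camera at the preset correlation called the same 11 lists in both. With the clone number as a block over the 4 arrays limma called 0 genes. That fit cannot weigh the calls, since clone numbers do not pair clones of different constructs. The block also lowered the moderated degrees of freedom to 3.1, from 3.98 with the 4 arrays alone.

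To find what coelacanth POU5F1 changes relative to mouse OCT4, the LcPOU5F1 clones were compared with the mOct4 clones. Naive pluripotency genes did not pass the test: Esrrb differed by -0.03 ± 0.40, Nanog by -0.29 ± 0.36, Sox2 by 0.27 ± 0.22, Klf4 by -0.40 ± 0.41 and Zfp42 by 0.28 ± 0.32. These standard errors pool the spread of all 6 arrays, with the LcPOU5F3 clones that are not compared here. For Esrrb the SD was 0.01 in mOct4, 0.07 in LcPOU5F1 and 0.87 in LcPOU5F3. For Nanog it was 0, 0.02 and 0.76 in that order, but for Klf4 it was 0.17, 0.69 and 0.51. Larger differences in the list, picked after their values were seen, were Fbxo15 at -1.21, Tet2 at -1.17 and Nr0b1 at 1.21. None of the 23 naive and none of the 20 general pluripotency genes passed over all genes, and adjusted over the list alone 0 and 1 did. Only 5 of 14595 genes were called by limma with Benjamini-Hochberg adjustment, and 2265 had an unadjusted p under 0.05. Nell1 rose at least 9.07-fold (adjusted p = 0.035) and Cubn, an endocytic receptor of visceral endoderm, at least 5.69-fold (adjusted p = 0.035). The homeobox gene Hoxb13 fell at least 8.31-fold (adjusted p = 0.029), the netrin receptor gene Unc5a at least 3.07-fold (adjusted p = 0.035) and the glutathione transferase gene Gstt1 7.08-fold (adjusted p = 0.035). Fewer than 10 genes passed in each direction, so these 5 are all that could be named by size.

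Cdx2 was 7.40-fold lower in the LcPOU5F1 clones, with 1 of their 2 arrays well above background, but did not pass (adjusted p = 0.23 by limma with Benjamini-Hochberg adjustment). Camera at the preset correlation placed the trophectoderm list lower (median log2 fold change -0.41, adjusted p = 0.00034, and adjusted p = 0.52 with an estimated correlation). No member passed over all genes, and adjusted over the list alone 10 were lower and 2 higher. The 2-cell-like list had a median of -1.97 over 15 members, or -1.07 with unmeasured members at their bounds. Members without a bound, such as Usp17le, keep their measured value there, so -1.07 may overstate the fall. The list's median was 0.09 over the 4 members well above background on all 6 arrays, which leaves out members that fell to background. None of its members passed over all genes and 8 were lower adjusted over the list alone (camera adjusted p = 9.5e-06, and adjusted p = 0.52 with an estimated correlation). Many of those genes are near-identical copies whose probes can read one another. The mesenchymal list (median -0.57, adjusted p = 0.00034), the glycolysis list (-0.15, 0.012), the formative list (-0.44, 0.023), the Hox list (-0.71, 0.023) and the germ cell list (-0.30, 0.033) were also placed lower by camera. With unmeasured members at their bounds, where these could be given, the medians were -0.36 for trophectoderm, -0.51 for mesenchymal, -0.42 for Hox and -0.09 for germ cell genes. The Hox median was 0.21 with no filter on dim probes, where the median of all genes was 0.222. The germ cell median was 0.28 over members well above background on all 6 arrays, which leaves out members that fell to background. The cell cycle list was placed higher by camera (0.20, adjusted p = 0.033). Centring arrays on their median moved all genes alike, from a median of 0.1 to -0.27, and that of the list to -0.17. The change of sign thus says nothing of the list against other genes. Each of these calls was lost: adjusted p = 0.57 with an estimated correlation for germ cell genes and 0.52 for the others.

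The count of genes depended on which arrays set the spread: limma called 537 genes, 178 higher and 359 lower, when only these 4 arrays were fitted, and 0 when either mOct4 clone or either LcPOU5F1 clone was left out. The split of calls was 2 higher and 3 lower with the 75th percentile, 7 and 101 with quantile normalization, and 47 and 703 with median centring.

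To set the paralogs against each other, the LcPOU5F1 clones were compared with the LcPOU5F3 clones. Naive pluripotency genes were higher with LcPOU5F1: Zfp42 by 5.74-fold (2.52 ± 0.32), Esrrb by 5.48-fold (2.45 ± 0.40), Sox2 by 3.88-fold and Nanog by 3.37-fold, although a second Nanog probe gave 0.09 where the one used gave 1.75. Cdx2 was 105-fold lower (-6.71 ± 0.77), with the LcPOU5F1 clones at -2.26 and -4.69 and 1 of their 2 arrays well above background. Krt8 was 33.3-fold lower (-5.06 ± 0.18). Limma with Benjamini-Hochberg adjustment called 2987 of 14595 genes, 1531 higher and 1456 lower with LcPOU5F1. That fit shares its spread with the mOct4 clones, which are not compared here and varied least. With only the 4 arrays compared it called 498 genes, so the calls and standard errors lean on the mOct4 pair. LcPOU5F3 stood apart from both other groups the same way in 2112 genes, higher in 1143 and lower in 969. Both comparisons use the same 2 LcPOU5F3 arrays, whose clones varied most, so error in those arrays can raise this count.

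Of 23 naive pluripotency genes, 17 were higher with LcPOU5F1 and 1, Dppa3, was at least 4.91-fold lower, with equal counts adjusted over the list alone (camera adjusted p = 1.6e-05, and adjusted p = 0.4 with an estimated correlation). Nr5a2, a nuclear receptor that binds Pou5f1 regulatory DNA, was 5.19-fold higher. Of 27 trophectoderm genes, 16 were lower and none higher (18 lower and 1 higher adjusted over the list alone), with Krt19 46.8-fold lower and Krt7 at least 32.0-fold lower (camera adjusted p = 4.1e-11, and adjusted p = 0.24 with an estimated correlation). Epithelial adhesion genes were lower in 12 of 23 (13 adjusted over the list alone), with Dsp 14.8-fold lower (-3.89, and -3.13 on a second probe; camera adjusted p = 1.5e-08, and adjusted p = 0.46 with an estimated correlation). Mesenchymal genes were lower in 10 of 20 (11 adjusted over the list alone), with Timp3 at least 79.5-fold lower and Tagln 69.1-fold lower (camera adjusted p = 2.8e-08, and adjusted p = 0.24 with an estimated correlation). Hox genes were lower in 10 of 16 (also 10 adjusted over the list alone), among them Hoxc9 at least 26.2-fold and Hoxb13 at least 5.80-fold (camera adjusted p = 8e-07, and adjusted p = 0.24 with an estimated correlation).

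Targets of p53 were lower in 11 of 23 (14 lower and 1 higher adjusted over the list alone), with Plk2 12.1-fold lower and Mdm2, the ubiquitin ligase that restrains p53, 3.03-fold lower (camera adjusted p = 3.9e-07, and adjusted p = 0.4 with an estimated correlation). Imprinted genes were lower in 7 of 20 (8 adjusted over the list alone), with Dlk1 14.5-fold and Peg3 5.01-fold lower (-2.32 for Peg3, and -1.13 on a second probe; camera adjusted p = 9.4e-05, and adjusted p = 0.24 with an estimated correlation). Cell cycle genes were higher in 13 of 28 (20 adjusted over the list alone), for example Mcm3 by 2.09-fold (camera adjusted p = 1.6e-05, and adjusted p = 0.36 with an estimated correlation). General pluripotency genes were higher in 8 of 20 and lower in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.041, and adjusted p = 0.74 with an estimated correlation). Formative and primed genes were lower in 8 of 20 and higher in 1 (8 and 2 adjusted over the list alone), with the WNT antagonist Dkk1 at least 5.73-fold lower (camera adjusted p = 0.047, and adjusted p = 0.45 with an estimated correlation). Among the genes with the largest fitted differences, Anxa1 was 159-fold lower, Thbs1 at least 71.2-fold lower and Tcl1 60.5-fold higher.

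Limma called 498 genes without either mOct4 clone, 685 without LcPOU5F1 clone 4, 487 without LcPOU5F1 clone 5, 5920 without LcPOU5F3 clone 1 and 1909 without LcPOU5F3 clone 2. With median centring the split was 502 higher and 1852 lower, and the median fold change of all genes moved from 0.21 to -0.2. Counts of list members by direction, such as those of cell cycle genes, depend on this scaling too.

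The departures of both coelacanth groups from the same mOct4 arrays were then set side by side. Across genes, which are not independent replicates, their log2 fold changes correlated with r = 0.37, against 0.20 (0.142 to 0.248) in 100 simulations of unchanged groups with shared controls. The covariance was 0.24 against a simulated 0.016, a difference of 0.224. Of the 5 genes called for LcPOU5F1, 1 higher and 2 lower genes were called the same way for LcPOU5F3, against 0.236 and 0.353 for independent lists and 0 in the simulations. The first leaves out the shared controls and the second the effects, so the overlap is not read as a shared effect. The mOct4 arrays were too few to give each comparison 2 of its own. With 1 mOct4 clone for each comparison, a split added after the correlation was seen, the covariance was 0.216 and 0.219. This argues against noise of shared control arrays as the source of most of the excess. What both mOct4 clones have in common stays in both comparisons.

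Clones of 1 construct lay closer to each other than to clones of another. The root mean square log2 difference over the tested genes was 0.297 within mOct4, 0.490 within LcPOU5F1 and 0.717 within LcPOU5F3. Between groups it averaged 0.663 for mOct4 and LcPOU5F1, 1.143 for mOct4 and LcPOU5F3 and 1.106 for LcPOU5F1 and LcPOU5F3. The first principal component held 67% of the variance and the second 16.6%. No test of this grouping was made, since 6 arrays allow too few ways of pairing.

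**Figure D2:**
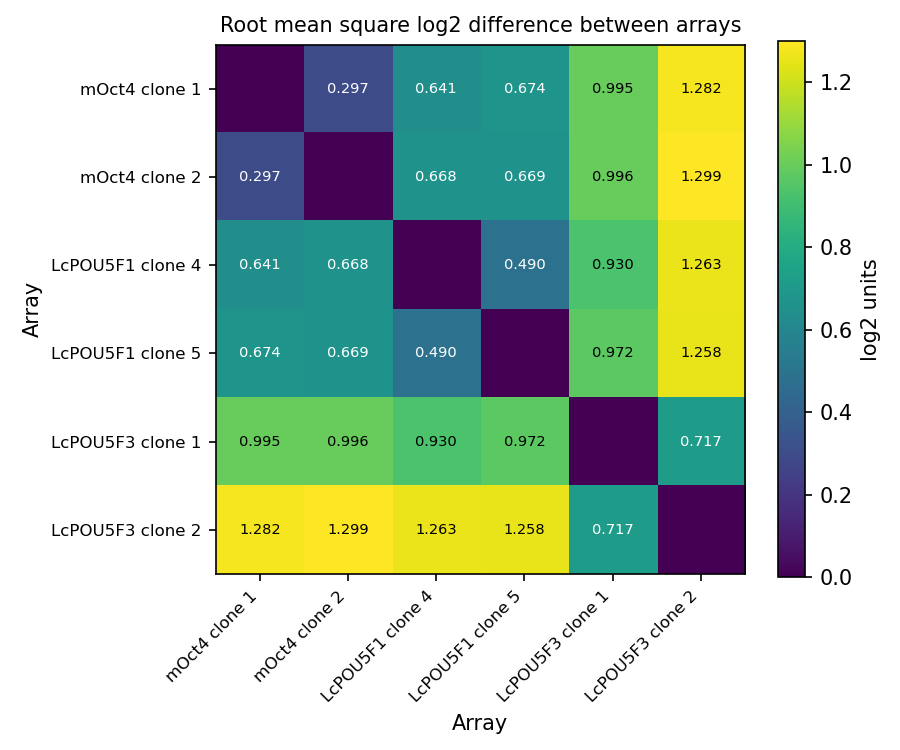
Root mean square log2 difference between each pair of the 6 arrays over the tested genes, in log2 units, with brighter colours for larger differences. The mOct4 pair is the closest at 0.297, and the pairs that join an LcPOU5F3 clone to another group lie between 0.93 and 1.299.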

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

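All tests of explanations in this part were chosen after the results were seen. Probes without a gene symbol were in no comparison of named genes, yet 923 of 12026 such probes changed between LcPOU5F3 and mOct4, 187 higher and 736 lower, by limma with Benjamini-Hochberg adjustment over every kept probe. Between LcPOU5F1 and LcPOU5F3, 827 changed, 662 higher and 165 lower. The shares were 7.68% and 6.88%, against 15.8% and 13.1% of probes with a symbol. Which transcripts they read was not examined.

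The fall of naive pluripotency genes and rise of trophectoderm genes in the LcPOU5F3 clones was set against technical explanations. Signals near background are argued against: the members well above background on all 6 arrays had medians of -1.78 (22 naive genes) and 1.5 (16 trophectoderm genes). A single divergent clone is argued against for the naive list, since the clone nearer to mOct4 still had a median of -1.40 and the other -1.90. Unchanged cells as the source of the whole remaining naive signal would keep every abundant gene at their share, which could not be decided. Of 7837 genes above the 75th percentile in all mOct4 and LcPOU5F1 clones, 52 lay more than 1 log2 unit below the naive median in both LcPOU5F3 clones, with dim signals raised to each array's floor. In 100 draws from the differences between the 2 LcPOU5F3 clones 0 to 1 did. Those draws leave out differences between constructs and the error of the mOct4 mean, so no conclusion is drawn from them. Gene by gene, a one-sided limma test with Benjamini-Hochberg adjustment placed 1 of 14379 genes below that median and 0 below it by more than 1. A smaller share of unchanged cells was not tested. An effect of the rescuing protein stays open, and with 2 clones per construct it may not be separable from how these colonies were picked.

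The 5 genes called between LcPOU5F1 and mOct4 with all arrays, against 537 with their own 4, were weighed in the same way. Clone spread was unequal, at 0.21 in mOct4, 0.346 in LcPOU5F1 and 0.507 in LcPOU5F3. Both fits give each gene the same log2 fold change (median over genes 0.098 in both). The 4-array fit had fewer moderated degrees of freedom (4.6 against 5.16). The counts therefore differ through the spread estimated for each gene, which the LcPOU5F3 clones enter only with all arrays. With a variance weight per group all 6 arrays called 504 genes, which goes with a pooled spread widened by the LcPOU5F3 clones. In simulated data with those spreads, the 4-array fit recovered 16.4% of genes changed by 1 on the log2 scale, the fit to all arrays 5.97% and the variance weight 46.3%. For genes changed by 2 the shares were 83.6%, 77.6% and 97%. The simulation scaled the spread of all genes of a group alike. Its shares differ far less than 5 and 537 calls do, so it does not decide this. Signals near background cannot be told apart from real differences for the rest, since 40.6% of the 537 genes were well above background on all 6 arrays. That share cannot decide it: the filter drops genes that fell to background in LcPOU5F1 and asks for signal in LcPOU5F3, which is not compared.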

How the results depend on the processing

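The variance weight per group, the common floor on dim signals, normexp on median signals and the split of the mOct4 clones were chosen after the data were seen.

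For LcPOU5F1 against mOct4 the count of 5 genes became 108 with quantile normalization, 13 with normexp, 29 with an intensity trend, 537 with only the 4 arrays compared, 504 with a variance weight per group, 21 at an adjusted p under 0.1, and 1 with a common floor. It was 0 by limma with no filter, with the filter on all 6 arrays, with every kept probe and with the slide as a block, where 2265 genes had an unadjusted p under 0.05 with all arrays. Leaving out 1 array gave 0 to 537. Centring on the median gave 750. That setting gave each array a different offset, from 2.62 to 3.45, and moved the median fold change of all genes from 0.10 to -0.27. The offsets inside groups alone gave 475 calls and raised the moderated degrees of freedom from 5.16 to 1120, while the offsets between groups alone gave 96. Its p-values therefore rest on a spread that the offsets themselves made alike between genes, and they are not read here as stronger evidence.

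For LcPOU5F3 against mOct4 the count of 3438 became 1541 with no filter, 2194 with only the 4 arrays, 41 with the slide as a block, and 5330 at an adjusted p under 0.1. Leaving out 1 array gave 35 to 5109. The clone numbers did not pair the clones (r = -0.0966 across genes), and with them as a replicate block 0 genes were called. For LcPOU5F1 against LcPOU5F3 the count of 2987 became 959 with no filter, 498 with only the 4 arrays or with the slide as a block, 1646 with a variance weight, and 4995 at an adjusted p under 0.1. Leaving out 1 array gave 487 to 5920. A left-out array leaves a lone clone that is assumed to vary like the others.

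For Pou5f1 in LcPOU5F1 against mOct4, -2.79 passed the threshold of limma with Benjamini-Hochberg adjustment with median centring (-3.16) and with only the 4 arrays (-2.79, adjusted p = 0.03). Leaving out either LcPOU5F3 clone gave the latter values again. It was -0.71 with normexp and -0.82 with a common floor without passing, and ranged from -3.16 to -2.43 with 1 array left out. In LcPOU5F3 against mOct4, -2.95 passed with quantile normalization (-2.63), median centring (-2.92), an intensity trend (-2.95), a variance weight (-2.95), a common floor (-0.82), and without LcPOU5F3 clone 1 (-4.33) or 2 (-1.58). It was -0.94 with normexp, and ranged from -4.33 to -1.58 with 1 array left out. Only 1 kept probe carried the Pou5f1 symbol, so no other was run.

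Of 8 lists called by camera for LcPOU5F1 against mOct4, 3 were called with the filter on all 6 arrays and 0 with an estimated correlation or fry, and 4 to 9 with 1 array left out. Camera with an estimated correlation called 0 lists in LcPOU5F3 against mOct4, where 11 were called, and 0 in LcPOU5F1 against LcPOU5F3, where 10 were. Fry called 12 and 8 there, of which 10 and 8 were also called by camera at the preset correlation. With 1 array left out the counts were 11 to 12 and 8 to 11.

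The correlation of the departures from mOct4, 0.37, became 0.323 with normexp, 0.429 with no filter, 0.31 with the filter on all 6 arrays or a common floor, and 0.315 to 0.408 with 1 array left out. It was 0.322 and 0.324 with 1 mOct4 clone for each comparison. The mean difference between arrays moved from 0.663 for mOct4 and LcPOU5F1 to 0.428 with normexp, 0.697 with quantile normalization, 0.747 with median centring, 0.822 with no filter, 0.501 with the filter on all 6 arrays and 0.511 with a common floor. For mOct4 and LcPOU5F3, 1.143 became 0.822, 0.935 and 0.934 with normexp, that filter and the floor, and for LcPOU5F1 and LcPOU5F3, 1.106 became 0.802, 0.922 and 0.923. Except where a construction names it, the cause was not tested. No named gene that was called turned its direction on the probe used under any alternative run. A second probe of Zfp352 gave 0.44 in LcPOU5F3 against mOct4, where the one used gave -1.81. The medians of 4 lists called by camera for LcPOU5F1 against mOct4 changed sign. Median centring moved cell cycle genes from 0.20 to -0.17, and all genes alike, from a median of 0.1 to -0.27. With no filter Hox genes went from -0.71 to 0.21, where the median of all genes was 0.222. With the filter on all 6 arrays germ cell genes went from -0.30 to 0.28 and 2-cell-like genes from -1.97 to 0.09, over 4 members. That filter leaves out members that fell to background. These changes are not read as reversals. Background differed between arrays, which limits genes near it.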

Other observations

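With only their own 4 arrays fitted, the genes that separated LcPOU5F1 from mOct4 included 9 of 15 2-cell-like genes, all lower in the LcPOU5F1 clones. Among them, picked after their values were seen, AF067061 was at least 65.1-fold lower (adjusted p = 0.0083 by limma with Benjamini-Hochberg adjustment), Zscan4f at least 54.8-fold lower (adjusted p = 0.024) and Tmem92 at least 3.14-fold lower (adjusted p = 0.014). These 3 were well above background on no LcPOU5F1 array, nor were Gm4340, Gm8300, Tcstv1 and Usp17le. No bound could be given for Usp17le. Zscan4a and Zscan4c were well above background on 1 of the 2 LcPOU5F1 arrays. Probes of near-identical copies can read one another, so the 9 are not independent. The fit to all arrays called no gene of the list in this comparison. The list was also placed lower in LcPOU5F3 against mOct4 (median -2.54, camera adjusted p = 0.023, and adjusted p = 0.7 with an estimated correlation). In the 4-array fit of LcPOU5F1 and mOct4, 4 of 27 trophectoderm genes were lower, which were Esx1, Hand1, Plet1 and Sct. Of the naive pluripotency list, 1 of 23 was called, the DNA demethylase gene Tet2, and it was lower.

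In the LcPOU5F3 clones, genes of several signalling and stress lists moved both ways against mOct4. Over all genes 23.6% were called in this comparison, 1723 higher and 1715 lower. Camera at the preset correlation called none of the lists given here. Its adjusted p was 0.5 for stress and heat shock, 0.87 for LIF and STAT3 targets and 0.59 for DNA methylation. Of 22 stress and heat shock genes 3 rose and 9 fell (4 and 9 adjusted over the list alone), and of 20 LIF and STAT3 targets 6 rose and 5 fell (6 and 6). The immediate early genes Fos (17.4-fold), of the latter list, and Atf3 (6.75-fold) rose, as did the heat shock gene Hspa1a (4.80-fold), while Nupr1 fell 9.38-fold and Trib3 5.36-fold. Among 18 genes of DNA methylation 2 rose and 4 fell, also adjusted over the list alone: Dnmt3l fell 20.1-fold and Tet1 4.99-fold, while Gadd45b rose 3.13-fold. Dnmt3l was about as low in the LcPOU5F1 clones (-4.45 against mOct4, adjusted p = 0.13 with all arrays and 0.039 with their own 4, by limma with Benjamini-Hochberg adjustment), and differed by -0.13 between the paralogs. Of the X-linked genes tested, Ddx3x, Eif2s3x, Kdm5c and Kdm6a, none was called in any comparison by limma with all arrays.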
